A study of Mus musculus with 6 samples.

How the data were processed

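RNA was extracted from whole uteri of 3 control and 3 Rest cKO mice aged 4 months, and libraries were made from total RNA with a TruSeq RNA kit (version 2), per the labels' protocols. The authors deposited a single table of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with 1 column per sample and 1 row per gene entry. STAR 2.5.2b, Cufflinks 2.2.1, bcl2fastq and the mouse build GRCm38 are listed in the submitters' processing notes, which give no roles, settings or annotation release. FPKM divides by transcript length and by mapped fragments, so a group of abundant transcripts in a library lowers all its other values. No rescaling between samples is stated, and the columns sum to different totals.

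The table held 38016 rows with 34422 distinct symbols, of which 13543 rows were 0 in every sample. Some rows carried identical values in all 6 samples, as merged loci give: 1315 of the 16418 rows tested shared their values with another row, leaving 15671 distinct value sets, and 342 rows had a repeated symbol. For genes sharing values with another entry (Gria2 among those named) the reads cannot be assigned to either. Whether counting used strand is not given in the sources used here. Coordinates were taken by gene symbol from GENCODE M21 on GRCm38, the same build but possibly another annotation release.

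Read counts are not given, so depth and counting error are unknown. Below 0.05 FPKM the values of a gene step by what a single fragment is worth, and the ratio of that step between 2 libraries is shared by all genes only if fragments were turned into FPKM alike. The share of such rows at the most frequent ratio (within 0.02 on the log2 scale) was 9.78 to 20.0% for 6 pairs of libraries and 3.37 to 4.68% for the other 9. The pairs with high shares form 2 sets: set 1 with control 2, control 4 and cKO 3, and set 2 with control 3, cKO 2 and cKO 4. The labels name no batch. These sets were found in the data and are used as a technical batch. Step sizes put relative depth within set 1 at 1.0, 0.946 and 1.01, and within set 2 at 1.0, 1.11 and 1.22, in the order given; between sets it cannot be compared.

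Values were taken as log2(FPKM + 0.5), and rows with a mean of at least 0.5 FPKM over the 6 samples were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, genotype alone in the model, two-sided). P-values were adjusted by Benjamini and Hochberg over all rows tested, with 0.05 as the threshold; changes of at least 2-fold had an absolute log2 fold change of at least 1. FPKM are not counts, so no count model was used. Labels do not say whether the numbers 2 to 4 mark litters or days, and a fit with the number as a block was an alternative. The labels describe separate mice only by their number per group, so p-values measure the spread between these 6 samples. For single values an exact permutation test was used, in which 3 against 3 cannot go below 0.1.

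In all, 23 gene lists were fixed before the data were examined: REST-repressed neuronal genes, progesterone and estrogen response, steroid receptors, matrix, TGF-beta, Wnt, leiomyoma, cell cycle, interferon and immediate early genes, and markers of the cell types a whole uterus can hold. They were written from general knowledge. Each was tested with limma's camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, which does not compare a list with other genes. The test, the thresholds and the rule for named genes were also fixed before the data were examined. Named were Rest, Amhr2, Pgr and Esr1, the 10 genes with the largest absolute log2 fold change in each direction among those past the threshold whose groups did not overlap (predicted genes and pseudogenes left out), and up to 4 members of each list with the smallest p; other genes are said to have been chosen after their values were seen. Some genes this rule takes are not reported here.

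The procedure was tested on simulated data with 200 changed genes in 10 runs over 16418 genes. It recovered 1.0%, 46.4%, 84.6% and 96.2% of genes changed 2-fold, 4-fold, 8-fold and 16-fold, 5.1% of calls were unchanged genes, data with no change gave at most 1 call, and a moved list of 40 genes was called in 10 of 10 runs. The simulated noise was independent between genes, and no library sets were simulated. Members of real lists were correlated, at 0.335 for the REST-repressed list, so these rates need not hold in the real data. There, splits other than by genotype gave up to 137 genes and 12 called lists.

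Alternatives fixed before the data were examined were pseudocounts of 0.1 and 1, no filter, a mean of at least 1 FPKM, scaling by size factors, quantile normalization, the replicate block, sample weights, robust eBayes, leaving out each library in turn, an estimated correlation, and camera on ranks. Added after the data were seen were library set as a covariate (also with an estimated correlation), the estrogen-responsive list as a covariate, identical rows counted once, and each library set alone. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the table and drew the plots.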

Results

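Gene expression was measured by RNA sequencing in whole uteri of 6 mice aged 4 months. Of these, 3 carried floxed Rest alleles together with Cre recombinase at the Amhr2 locus (Rest cKO) and 3 carried the floxed alleles alone (control). REST is a zinc finger repressor that keeps neuronal genes silent outside the nervous system. Amhr2 encodes the anti-Müllerian hormone receptor, and Cre from its locus acts in cells derived from the Müllerian duct mesenchyme, so that a whole uterus also holds cells that never had the enzyme. Samples carry the numbers 2, 3 and 4 in each group. The values were FPKM, which summed to between 943901 (cKO 3) and 1407266 (cKO 2) per library, and the number of reads behind them is unknown. Of 38016 rows, 16418 had a mean of at least 0.5 FPKM and were tested. Spearman's rho over these rows, across genes, which are not independent replicates, was 0.86 to 0.911 between libraries of the same group and 0.84 to 0.921 over every pair.

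The first comparison asked how the targeted gene itself stood in each group. Rest (chromosome 5, 77265491 to 77286432, plus strand, GRCm38) had 20.1, 21.7 and 18 FPKM in control 2, 3 and 4, and 20.4, 20.9 and 16.1 FPKM in cKO 2, 3 and 4. The means were 19.9 ± 1.86 in control and 19.1 ± 2.68 FPKM in cKO (SD, n = 3 each; exact two-sided permutation p = 0.7, where 3 against 3 cannot go below 0.1). The log2 difference, cKO minus control, was -0.06 with a limma 95% interval of -0.66 to 0.53. Whole-gene FPKM adds up all exons and the labels do not name the floxed part, so these values check neither the deletion nor the genotype labels. Amhr2 (chromosome 15, 102445367 to 102454633, plus strand) had 2.07 ± 2.21 FPKM in control and 0.476 ± 0.15 in cKO (n = 3 each; limma adjusted p = 0.998), with 4.57 FPKM in control 3 alone. Esr1, the main estrogen receptor of the uterus, had 150 ± 22.2 FPKM in control and 143 ± 73.1 in cKO (limma adjusted p = 0.998). Pgr, the progesterone receptor, had 72.1 ± 82.9 in control and 77.6 ± 25.2 in cKO (limma adjusted p = 0.998), and its control values ran from 19.2 to 168 FPKM.

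The second comparison asked which genes differed between Rest cKO and control uteri. In cKO uteri 17 genes were higher and 0 lower (limma, Benjamini-Hochberg adjusted p under 0.05), all by at least 2-fold, and in all 17 the 3 cKO values lay above the 3 control values. Ptprn, a membrane protein of dense-core secretory granules, rose the most, from 0.826 ± 0.622 to 45.7 ± 12.6 FPKM (SD, n = 3; log2 fold change 5.21, SE 0.438; limma adjusted p = 0.0263). Chga, which encodes the granule protein chromogranin A, rose from 0.844 ± 0.622 to 25.2 ± 4.90 FPKM (log2 fold change 4.36, SE 0.437; limma adjusted p = 0.0263). Stmn3, a neuronal microtubule regulator of the stathmin family, rose from 3.75 ± 1.73 to 67.2 ± 31.7 FPKM (log2 fold change 3.96, SE 0.433; limma adjusted p = 0.0303). These log2 fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. In GRCm38, Ptprn lies on chromosome 1 (75247027 to 75264502, minus strand), Chga on chromosome 12 (102554969 to 102565028, plus strand) and Stmn3 on chromosome 2 (181306459 to 181314500, minus strand), each a protein-coding gene.

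Scg3, which encodes the granule protein secretogranin III, went from 1.56 ± 0.238 to 28.1 ± 9.92 FPKM. Chrnb2, a subunit of neuronal nicotinic acetylcholine receptors, went from 0.375 ± 0.0753 to 9.73 ± 3.15 FPKM. Nppa, the precursor of atrial natriuretic peptide, went from 0.492 ± 0.338 to 12 ± 4.50 FPKM. Nrsn1, a neuronal vesicle protein, had 0.0694 ± 0.00934 FPKM in control and 7.36 ± 2.34 in cKO. Tnr, the extracellular matrix protein tenascin-R of the nervous system, had 0.226 ± 0.168 FPKM in control and 7.84 ± 1.35 in cKO. Lrp11 reached 38.3 ± 8.0 FPKM from 2.70 ± 0.622, with the smallest p of the 17. Tmem179 reached 7.62 ± 2.36 FPKM from 0.179 ± 0.0827. Those 10 genes had the largest log2 fold changes of the 17 on the log2(FPKM + 0.5) scale. By the ratio of mean FPKM the order differs: Nrsn1 had 106, Mmp24, outside the 10, 59.6, and Ptprn 55.3. The other 7, named after their values were seen, also rose: Mmp24, Maneal, Crmp1, Hpca, Gprin1, Rundc3a and Rasl10b, with log2 fold changes of 3.37, 3.20, 3.14, 3.04, 3.04, 2.90 and 2.79.

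**Figure D1:**
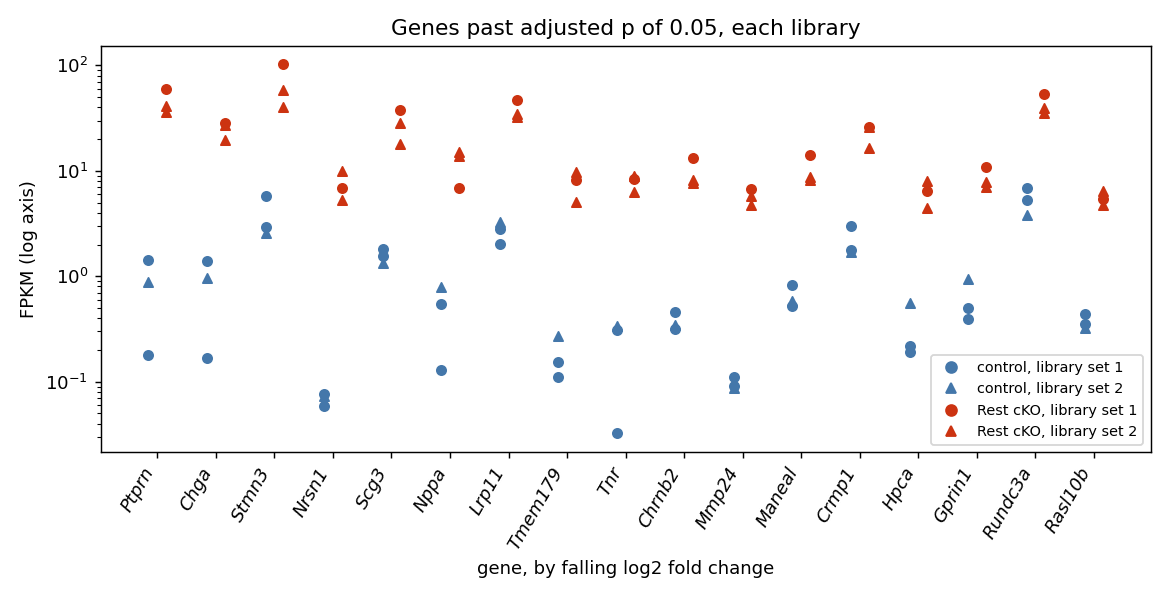
FPKM on a log axis of the 17 genes past the threshold, 1 point per library, with control in blue and Rest cKO in red, and circles and triangles for library sets 1 and 2. In each gene the 3 cKO points lie above the 3 control points, as for Ptprn at 0.179 to 1.42 FPKM in control and 36.2 to 59.9 in cKO.

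At an unadjusted p under 0.05, 230 rows were higher and 167 lower, 2.42% of the rows tested. These counts rested on single libraries: they were 571 and 850 without control 3 and 618 and 712 without cKO 3, so that more were lower, and 208 and 77 without control 2, 223 and 56 without control 4, 195 and 72 without cKO 2 and 221 and 141 without cKO 4. With all libraries the 50 smallest p-values all belonged to higher rows. The smallest limma adjusted p of a lower row was 0.622. Groups did not overlap in 902 rows (5.5%), where chance gives 10% for 3 against 3. In simulated data with these genes and samples, and noise independent between genes, the test recovered 1.0% of genes changed 2-fold. It recovered 46.4% of those changed 4-fold and 84.6% of those changed 8-fold, so most 2-fold changes would not be detected. The low FPKM values fell into 2 library sets, described under processing: set 1 held control 2, control 4 and cKO 3, and set 2 held control 3, cKO 2 and cKO 4. With library set in the model 0 genes passed, and so 0 of the 17 (smallest limma adjusted p = 0.0737, with 321 rows at an unadjusted p under 0.05). The median log2 fold change of the 17 was 3.50 against 3.54 without it. The median of the 17 single-gene SEs was 0.347 in both fits, and residual degrees of freedom fell from 4 to 3. Within set 1 the 17 had log2 fold changes of 2.74 to 5.73, and within set 2 of 2.45 to 4.82. With 1 library left out, 0 of the 17 passed in any of the 6 fits, though all 17 stayed higher; other genes passed in 2 of them, 1 without control 3 and 2 without cKO 3.

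Genes repressed by REST, a list fixed before the data were examined, were higher in cKO as a group. Of 47 members tested, 45 had a positive log2 fold change, with a median of 1.72. Over all genes tested, 6 rose, 0 fell and 41 did not pass; adjusted over the list alone, 33 rose, 0 fell and 14 did not pass. The groups did not overlap, with cKO higher, in 34 members. Those that rose over all genes were Ptprn, Scg3, Chrnb2, Chga, Stmn3 and Rundc3a, 6 of the 17 genes where 0.0487 would be expected (Fisher's exact two-sided p = 4.78e-12). That test treats genes as independent, which members of the list were not, so its p-value is descriptive only and does not measure the spread between libraries. Camera called the list with a preset correlation (adjusted p = 5.18e-63), and did not with an estimated correlation of 0.335 (adjusted p = 0.163 with an estimated correlation). Fry, which tests whether the members move one way on balance, gave an adjusted p = 0.0415 over the 23 lists (limma). The median was 2.27 within library set 1 and 1.55 within set 2.

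Some members passed only when adjusted over the list alone. Gria2, a glutamate receptor subunit, had 0.985 ± 0.491 FPKM in control and 5.17 ± 2.92 in cKO (limma adjusted p = 0.962 over all genes and 0.0132 over the list alone), although its row holds the same values as that of another entry. Stmn2, a relative of Stmn3, had 2.26 ± 1.01 and 6.67 ± 2.93 FPKM (limma adjusted p = 0.998 over all genes and 0.027 over the list alone). Others passed neither way. Chosen after its values were seen, the kinesin gene Kif5c had 20.3 ± 6.03 FPKM in control and 13.3 ± 4.66 in cKO (limma adjusted p = 0.998), and the splicing regulator Srrm4 had 0.880 ± 0.489 and 1.41 ± 0.950. In addition, 11 matched members lay under the level tested. Of those, 5 had all cKO values above all control values: Vgf, Glra1, Glra3, Cdk5r2 and Rab3c, each with a cKO mean between 0.391 and 0.775 FPKM. Nefl, which encodes the light chain of neurofilaments, had 0.00344 FPKM in control and 0.0114 in cKO, and Bdnf 0.125 and 0.0614.

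**Figure D2:**
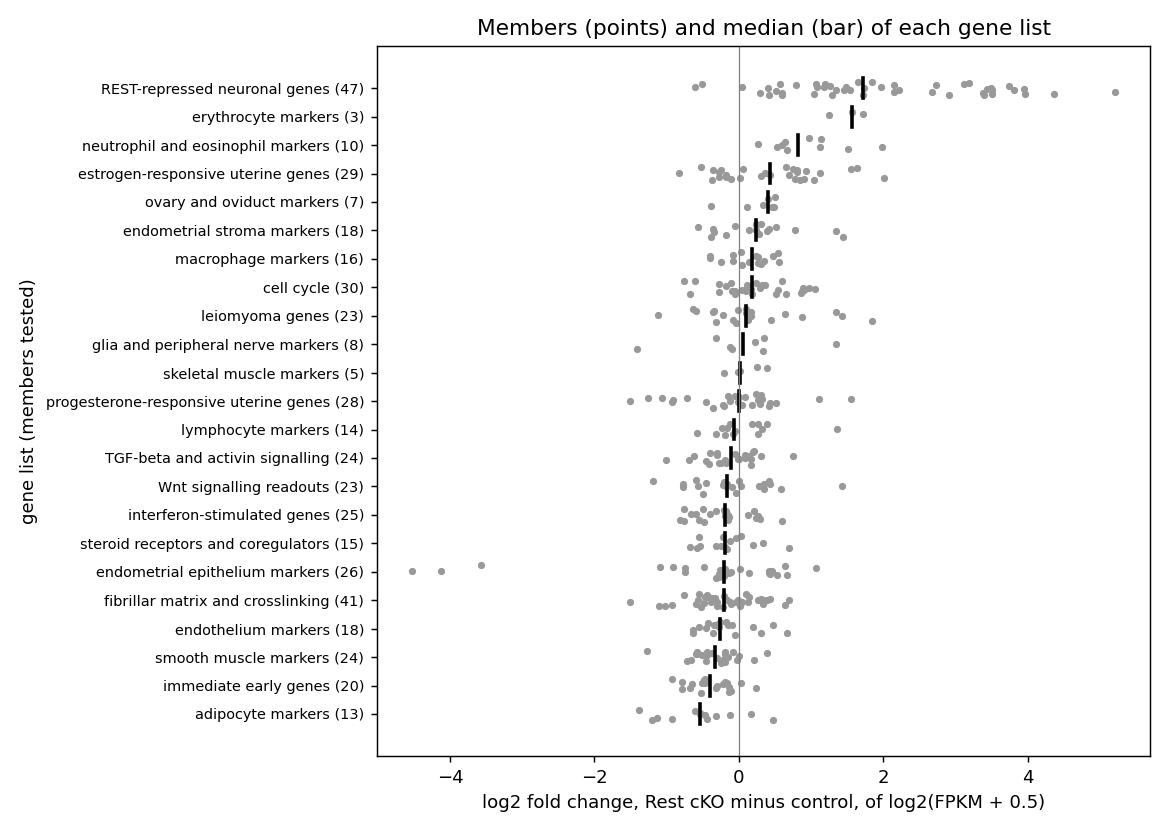
Log2 fold change, Rest cKO minus control, of each tested member (points) and the median (bar) of 23 gene lists; the number tested stands behind each name and points are spread vertically for legibility. The REST-repressed list has the highest median, 1.72, and the adipocyte list the lowest, -0.54.

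The title of the series names the progesterone receptor and leiomyoma, a benign tumour of uterine smooth muscle, so hormone response, matrix and tumour genes were compared as groups. For the single genes given here and below, outside the 17, direction held within each library set wherever the groups did not overlap. In lists other than the REST-repressed one these were Lifr, Foxo1, Gria2, Stmn2, Postn, Col12a1, Hmga2, Fosb, Myh11 and Smtn. Where the groups overlapped, direction within each set should not be assumed, as many genes turned there. Of 28 progesterone-responsive genes, 14 had positive and 14 negative log2 fold changes, with a median of 0.00 (-0.003), and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.917). Without control 4 camera called it higher (median 0.35, adjusted p = 0.0191). Its members with the smallest p were Lifr, a cytokine receptor gene, at 17.5 ± 8.04 FPKM in control and 7.38 ± 0.0889 in cKO, Foxo1 at 25.3 ± 2.73 and 15.6 ± 4.48, Alox15 at 74.7 ± 32.7 and 41.2 ± 22.7, and Hsd11b2 at 93.2 ± 122 and 169 ± 109 (limma adjusted p = 0.998 for each). The estrogen-responsive list had a median of 0.43 over 29 members and 0 passing either way (camera adjusted p = 0.174), and was called higher without control 2 (0.77, 0.000102) or cKO 3 (0.65, 0.0216); in it Mcm2 had 8.82 ± 8.05 FPKM in control and 13.5 ± 2.99 in cKO, and Greb1 13.5 ± 11.2 and 19.6 ± 7.14. Estrogen-responsive genes spread widely within each group: Ltf, the lactotransferrin gene, chosen after its values were seen, had 1870, 29.7 and 23.6 FPKM in control 2, 3 and 4 and 1330, 33.8 and 308 FPKM in cKO 2, 3 and 4. Steroid receptors and coregulators had a median of -0.20 over 15 members with 0 passing (camera adjusted p = 0.203), and were called lower without cKO 3 (-0.43, 0.0347).

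Fibrillar matrix genes had a median of -0.21 over 41 members, 0 of which passed over all genes or adjusted over the list alone (camera adjusted p = 0.126). Camera called them lower without control 2 (-0.45, 0.00178) or control 4 (-0.39, 0.0017), and with library set as a covariate (-0.312, 0.00379). Their median turned between the library sets, from 0.43 within set 1 to -0.945 within set 2. Postn, which encodes the matrix protein periostin, had 118 ± 57.5 FPKM in control and 36.8 ± 1.72 in cKO, Fap 6.30 ± 2.40 and 2.61 ± 1.11, and Col12a1 6.74 ± 2.64 and 3.41 ± 1.56 (limma adjusted p = 0.998 for each). Genes tied to leiomyoma had a median of 0.09 over 23 members with 0 passing (camera adjusted p = 0.405); beside Gria2 and Stmn2, Hmga2, a chromatin protein rearranged in such tumours, had 5.76 ± 1.58 FPKM in control and 3.50 ± 0.710 in cKO. In the pathway lists of TGF-beta and activin (24 members, median -0.11, camera adjusted p = 0.535), Wnt (23, -0.16, 0.564), cell cycle (30, 0.18, 0.0756) and interferon-stimulated genes (25, -0.19, 0.284), 0 members passed. Camera called Wnt genes lower without cKO 2 (-0.37, 0.00758), cell cycle genes higher without control 3 (0.98, 7.61e-08), cKO 2 (0.52, 0.000874) or cKO 3 (0.45, 0.0216), and interferon-stimulated genes higher without control 2 (0.31, 0.00951) but lower without control 4 (-0.50, 0.00195) or cKO 2 (-0.76, 1.23e-05). Immediate early genes had a median of -0.39, with 18 of 20 members negative and 0 passing over all genes or adjusted over the list alone; camera called them lower (adjusted p = 0.0298; adjusted p = 0.843 with an estimated correlation). In that list Fosb had 0.868 ± 0.258 FPKM in control and 0.373 ± 0.176 in cKO, and Nr4a2 3.95 ± 1.79 and 2.10 ± 1.20, and the median was -0.85 within library set 1 and 0.18 within set 2. That call was lost without control 2 (median -0.18, camera adjusted p = 0.175) or cKO 3 (-0.07, 0.706).

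Markers of the cell types of the uterus were compared in the same way. Smooth muscle markers, which stand for the myometrium, had a median log2 fold change of -0.33, and 21 of 24 were negative. Camera called that list lower with a preset correlation (adjusted p = 0.00846; adjusted p = 0.843 with an estimated correlation), while 0 members passed over all genes or adjusted over the list alone. Myh11, the smooth muscle myosin heavy chain, had 315 ± 108 FPKM in control and 126 ± 26.8 in cKO, Lmod1 33.6 ± 12.4 and 19.6 ± 5.51, and Smtn 82.5 ± 7.91 and 58.7 ± 12.8 (limma adjusted p = 0.998 for each). The median was -0.30 within library set 1 and -0.15 within set 2, and without cKO 2 the call was lost (median -0.23, camera adjusted p = 0.0858).

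Blood cell markers were compared next. Neutrophil and eosinophil markers were called higher (10 members, median 0.82, camera adjusted p = 0.00846; adjusted p = 0.843 with an estimated correlation), as were erythrocyte markers (3 members, median 1.57, camera adjusted p = 0.0147; adjusted p = 0.843 with an estimated correlation), with 0 members of either passing over all genes or adjusted over the list alone. S100a9, a calcium-binding protein of neutrophils, had 0.638 ± 0.661 FPKM in control and 21.6 ± 36 in cKO. Hba-a1, an alpha globin gene, had 31.2 ± 25.4 and 133 ± 115 FPKM, and Alas2, which starts haem synthesis in erythroid cells, 0.912 ± 0.742 and 3.34 ± 2.87. Within library set 1 the neutrophil list had a median of -0.66 and the erythrocyte list of -0.61, and within set 2 they had 2.03 and 2.98. The neutrophil call was lost without cKO 2 (median 0.04, camera adjusted p = 0.886) or control 3 (0.31, 0.237). The erythrocyte call was lost without control 2 (1.16, 0.0636), control 3 (1.42, 0.147), cKO 2 (1.23, 0.0559) or cKO 4 (0.78, 0.125).

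**Figure D3:**
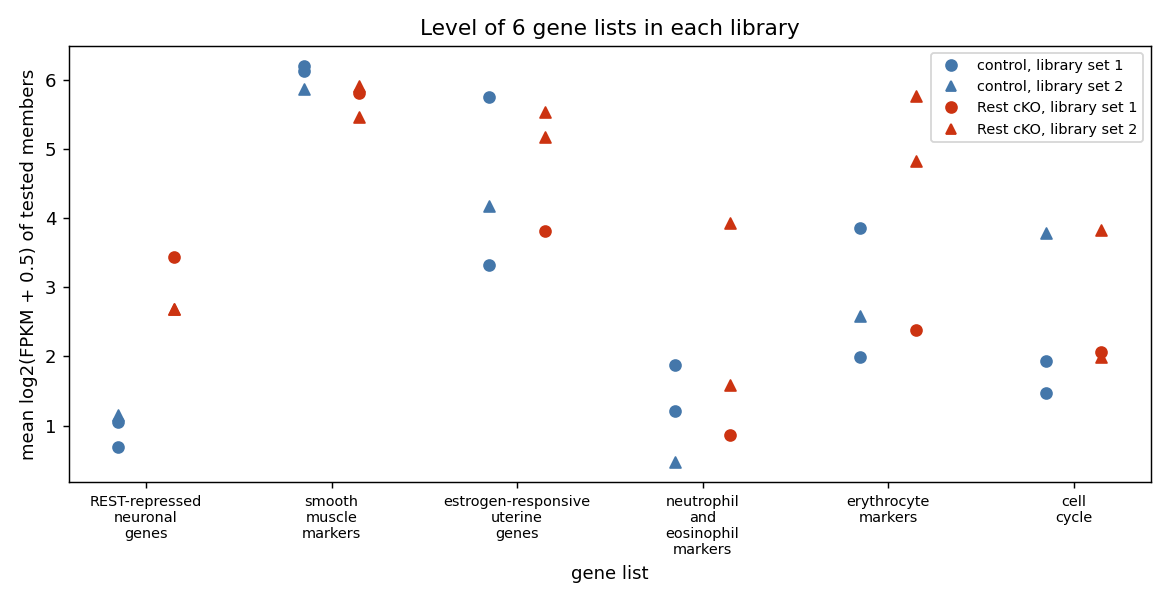
Mean log2(FPKM + 0.5) over the tested members of 6 gene lists, 1 point per library, with control in blue and Rest cKO in red, and circles and triangles for library sets 1 and 2. In the REST-repressed list the cKO libraries lie at 2.69 to 3.44 and the controls at 0.69 to 1.16; in the cell cycle list control 3 and cKO 4, of set 2, lie highest at 3.79 and 3.83.

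The remaining cell type lists had 0 members passing over all genes or adjusted over the list alone, and camera called none with all 6 libraries. Endometrial epithelium markers had a median of -0.20 over 26 members (camera adjusted p = 0.535). In that list the secretory genes Spink3 and Prss28 had 454 ± 764 FPKM in control against 1.36 ± 1.77 in cKO and 453 ± 779 against 1.11 ± 1.64, and control 4 alone, with 1340 and 1350 FPKM, set the control means. Medians were 0.23 for endometrial stroma (18 members, camera adjusted p = 0.2), -0.27 for endothelium (18, 0.269), 0.19 for macrophages (16, 0.516), -0.06 for lymphocytes (14, 0.564), -0.54 for adipocytes (13, 0.19), 0.41 for ovary and oviduct (7, 0.179) and 0.02 for skeletal muscle (5, 0.564). Glia and peripheral nerve markers had a median of 0.06 over 8 members (camera adjusted p = 0.945). For this list and the lymphocytes the sign of the median was opposite to the direction of camera. Most of these medians turned between library sets 1 and 2: macrophages -1.275 and 1.783, lymphocytes -0.518 and 0.855, adipocytes -1.811 and 0.879. Epithelium had -1.25 and 0.817, stroma 0.852 and -0.268, endothelium 0.111 and -0.335, and skeletal muscle 0.617 and -0.131. Ovary and oviduct (0.251 and 0.141) and glia and nerve (-0.038 and -0.175) kept 1 sign. With 1 library left out camera called several of these lists: higher, stroma without control 3 (0.60, 0.0312) or cKO 4 (0.39, 0.0428), macrophages without control 2 (0.76, 0.000425) or cKO 3 (0.58, 0.0185) and lymphocytes without control 4 (0.31, 0.00213); lower, epithelium without cKO 2 (-0.49, 0.0249), endothelium without control 2 (-0.31, 0.00829) and adipocytes without control 3 (-1.07, 0.0312) or cKO 2 (-0.99, 7.72e-05).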

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

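Covariates for library set and for the estrogen-responsive list, each library set alone and identical rows counted once were chosen after the data were seen. The 17 higher genes stayed higher under every alternative, but whether they passed the threshold did not hold. All 17 passed with a pseudocount of 1, size-factor scaling, sample weights or identical rows counted once, 15 with quantile normalization or robust eBayes, 14 with a mean of at least 1 FPKM or the estrogen-responsive list as a covariate, 13 with a pseudocount of 0.1, and 0 in the other fits, those without 1 library included. The number of all genes passing, main value 17, was 29 with size-factor scaling and 36 with sample weights, and was 0 with no filter (more rows tested), 0 with the replicate block, 0 with library set as a covariate, 0 in library set 1 alone and 1, a lower gene, in set 2 alone; the counts of genes changed at least 2-fold were the same numbers (29, 36, 0, 0, 0, 0 and 1). At an unadjusted p under 0.05 these 4 fits with 0 calls gave 649, 390, 321 and 1191 rows, set 2 alone 743 and sample weights 2009 (806 higher and 1203 lower), against 397 (230 and 167) as the main value; without control 3 there were 1421 (571 and 850) and without cKO 3 1330 (618 and 712). Leaving out 1 library gave 0 to 2 genes, and 0 to 2 changed at least 2-fold: 1 without control 3, 2 without cKO 3 and 0 without any of the other 4, none of them among the 17. The fits that kept 0 of the 17, other than that with no filter, had fewer samples or residual degrees of freedom. Fewer degrees of freedom did not always remove the calls: the fit with the estrogen-responsive list as a covariate also had 3, as did that with library set, yet kept 14. The cause of these and the smaller losses was not tested. Other settings gave 14 to 25 genes.

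Whether the replicate numbers pair the samples could not be decided. Same-numbered libraries had correlations of deviations of 0.262, -0.141 and -0.242, and not every library correlated best with its own number. Every same-numbered pair joins libraries of different library sets, so a lack of pairing cannot be told apart from the difference between the sets. With the replicate block 0 genes and 9 gene lists passed, and the glia and nerve list had a median of 0.064 with the direction of its test turned.

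The REST-repressed list was higher under all 23 alternatives, with medians of 1.26 to 2.27, and passed camera in all 21 with a preset correlation; its median of 1.72 did not pass with an estimated correlation (adjusted p = 0.163), nor its 1.94 with library set as a covariate and an estimated correlation (adjusted p = 0.268). With an estimated correlation 0 lists passed, and 0 with library set as a covariate and an estimated correlation. The number of lists passing was 10 with the estrogen-responsive list as a covariate, 12 in library set 1 alone, 13 in set 2 alone and 5 to 9 without 1 library. The smooth muscle list was lower under all 23 alternatives, with medians of -0.517 to -0.154, and passed in 19 of the 21 with a preset correlation.

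Rest went from -0.062 to 0.137 in library set 1 alone, stayed negative in library set 2 alone, and lay between -0.132 and 0.056 without 1 library. Without 1 library, Cpe lay between -0.893 and 0.232, Esr1 between -0.558 and 0.048, Ltf between -0.106 and 3.16, and S100a9 between -0.015 and 3.48. Cpe turned to 0.072 with sample weights, and Ltf to -0.056 with the estrogen-responsive list as a covariate. None of these passed in any of those fits. Apart from the 17 as a group, Rest is the only single gene fitted within each library set alone that is reported. The others were left out after many were seen to turn there. Unless the groups did not overlap, their direction within a set should not be assumed.

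Lists for which the direction of camera turned had the following medians; the median itself did not turn in every case, as for progesterone at -0.003 with no filter and lymphocytes at -0.135 with sample weights. With no filter, progesterone had -0.003 and glia and nerve 0.043; with a mean of at least 1 FPKM glia and nerve had 0.273; with camera on ranks progesterone had -0.003 and glia and nerve 0.064. With sample weights Wnt had 0.011, interferon 0.058, epithelium 0.031 and lymphocytes -0.135. With library set as a covariate progesterone had 0.156 and cell cycle -0.389, under either correlation. With the estrogen-responsive list as a covariate progesterone had 0.117, macrophages -0.079 and glia and nerve 0.003. In library set 1 alone progesterone had 0.397, estrogen -0.628, steroid receptors -0.050, matrix 0.430, endothelium 0.111, macrophages -1.275, neutrophils -0.657, lymphocytes -0.518, glia and nerve -0.038 and erythrocytes -0.608. In set 2 alone leiomyoma had -0.285, cell cycle -0.908, interferon 0.775, immediate early genes 0.176, epithelium 0.817, stroma -0.268, adipocytes 0.879, ovary 0.141 and skeletal muscle -0.131. Without 1 library the ranges were -0.208 to 0.017 for TGF-beta, -0.374 to 0.174 for Wnt, -1.072 to 0.112 for adipocytes, -0.589 to 0.979 for cell cycle, -0.494 to 0.265 for epithelium, -0.109 to 0.602 for stroma, -0.143 to 0.771 for estrogen, -0.447 to 0.092 for matrix, -0.251 to 0.011 for glia and nerve, -0.758 to 0.313 for interferon, -0.422 to 0.305 for lymphocytes, -0.352 to 0.758 for macrophages and -0.249 to 0.350 for progesterone. Some lists not called in the main analysis were called by camera in other fits. Without 1 library these were, without control 2, estrogen, matrix, interferon, endothelium and macrophages; without control 3, cell cycle, stroma and adipocytes; without control 4, progesterone (0.350, adjusted p = 0.0191), matrix, interferon and lymphocytes; without cKO 2, Wnt, cell cycle, interferon, epithelium and adipocytes; without cKO 3, estrogen, steroid receptors, cell cycle and macrophages; and without cKO 4, stroma. Interferon was called higher at 0.313 without control 2 (adjusted p = 0.00951) and lower at -0.503 without control 4. Ovary was called with no filter; estrogen, cell cycle, interferon and adipocytes with the replicate block; estrogen and cell cycle with sample weights; matrix with library set as a covariate; and cell cycle, interferon, epithelium, stroma and adipocytes with the estrogen-responsive list as a covariate. Library set 1 alone called matrix, cell cycle, interferon, epithelium, stroma, macrophages, lymphocytes and adipocytes, and set 2 alone called these and estrogen and endothelium; of the 8 called in both, all turned direction between the sets. The cause was not tested.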

Other observations

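All gene groups in the first 2 paragraphs were chosen after the data were seen, and the tests of explanations below were written after values bearing on them were seen, except 2 on the smooth muscle list, those of other splits and of transcript length. Of 12 genes of dense-core secretory granules, 11 had all 3 cKO values above all 3 control values, and the median log2 fold change was 3.14; 3 (Ptprn, Chga and Scg3) passed limma over all genes, 9 did not, and 6 belong to the REST-repressed list. Resp18 had 0.283 ± 0.320 FPKM in control and 17.7 ± 11.7 in cKO (SD, n = 3; limma adjusted p = 0.0616), Scg2 0.669 ± 0.461 and 11.8 ± 4.82, Chgb 0.350 ± 0.311 and 9.03 ± 3.68, and Ptprn2 0.344 ± 0.293 and 6.11 ± 3.55. The exception was Cpe, which encodes the prohormone-processing carboxypeptidase E and was already abundant, at 67.4 ± 24.9 FPKM in control and 70.8 ± 63.1 in cKO. Because these genes were picked from genes seen to be high, no test of the group is given.

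Regulators of neuronal splicing were mixed. Of 10 tested, 4 had cKO values all above control values and 0 passed limma over all genes: Srrm3 had 0.344 ± 0.320 FPKM in control and 8.66 ± 4.84 in cKO, Celf3 0.674 ± 0.628 and 9.50 ± 2.02, and Celf6 0.246 ± 0.115 and 4.87 ± 1.75, while Srrm4 had 0.880 ± 0.489 and 1.41 ± 0.950. Genes of the REST corepressor complexes showed no such shift: over 12 of them the median log2 fold change was -0.06, the lowest -0.71 and the highest 0.60, and 0 had cKO values all above control values.

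The rise of REST-repressed genes in cKO was weighed against 3 other readings. Other splits of the 6 libraries are too few, 10, for a share under 0.05: 2 gave as many genes as the real split, the real one with 17 and the highest other with 137, with the same 2 and 137 for genes changed at least 2-fold; 9 gave as many called lists (5 in the real split, at most 12 in another), and 1, the real one, gave as large a median of the REST-repressed list (1.72, highest other 0.946). The unequal share of library sets in the genotypes is argued against by medians of 2.27 and 1.55 within the sets. Nerve tissue in the cKO samples stays open: the 19 matched glia and nerve markers had a median log2 difference of 0.04, but 11 lay under 0.5 FPKM, where the pseudocount holds differences near 0, and members went both ways, with Vip at 0.0126 FPKM in control and 0.977 in cKO and Dbh at 0.234 and 0.589. Loss of repression by REST remains a hypothesis; no value here tests it apart from the rise of the list itself. Other cells with secretory granules, and animal-to-animal differences tied to genotype, were not tested. All cKO mice carried Cre at the Amhr2 locus and no control did, so effects of Cre or of the altered locus cannot be told apart from those of Rest.

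The split with 137 genes was that between the 2 library sets and points to a structure of the samples that crosses genotype, unequally. Of those 137, 69 were higher and 68 lower in set 2, and 62 (45.3%) were small RNA, histone or pseudogene rows, against 3.36% of the other rows (Fisher's exact p = 4.63e-52). This test was written after values bearing on it were seen, and rows of a class are not independent, so the p-value is descriptive only. Snora78 had 96.1, 92 and 76.7 FPKM in control 2, control 4 and cKO 3, against 1770, 4350 and 2120 in control 3, cKO 2 and cKO 4. In the same order Hist1h3h had 4.17, 4.87 and 5.32 against 60.8, 40.7 and 171. Such transcripts mostly lack a poly(A) tail or have near-identical parent genes, so a difference in library preparation or read handling is a candidate explanation. More dividing cells in set 2 stay open as a part of it. The cell cycle list had a median difference of 1.31, below the 2.07 of histone rows, and 0 of its 30 members were called between the sets. Its bootstrap 95% interval of 1.18 to 1.51 was drawn over genes, so it does not measure the spread between libraries. In set 2, control 3, cKO 2 and cKO 4 had cell cycle levels of 3.79, 1.99 and 3.83, so cKO 2 had the level of set 1. With library set in the model the 17 genes had a median log2 fold change of 3.50, and 0 of them passed (smallest limma adjusted p = 0.0737).

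The lower level of smooth muscle markers in cKO was weighed in the same way. Of the 10 splits, 3 moved the list's median as far (0.333 in the real split, highest other 0.492), and they are too few for a share under 0.05. Longer transcripts were lower in cKO (Spearman's rho of log2 fold change with transcript length -0.264 across genes, which are not independent). After removing that trend the median was -0.30 against -0.33 before, with a 95% interval of -0.44 to -0.12 from a bootstrap over genes. That interval does not measure the spread between libraries. With library set in the model the median was -0.26 (camera adjusted p = 0.00928). In these 6 libraries the medians argue against the length trend as the whole cause. For the library sets they cannot decide. The mean level of the list was 5.87 in control 3, 5.47 in cKO 2 and 5.91 in cKO 4, which share a set, so the lower level there rested on cKO 2. A smaller share of myometrium in the cKO samples, or a change within smooth muscle cells, may underlie it; neither was tested, and the call was lost with an estimated correlation (adjusted p = 0.843).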
